A study of Talpa occidentalis with 2 samples.

How the data were processed

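The series profiled the contacts of the FGF9 promoter by circular chromosome conformation capture with sequencing (4C-seq) in embryos of the Iberian mole, Talpa occidentalis. In 4C-seq, fixed chromatin is cut, ligated, cut again and amplified by inverse PCR from a chosen viewpoint, so that the sequenced partners report which fragments lay near the viewpoint. Per the labels' protocols, NlaIII made the first digest and DpnII the second, and the viewpoint of both libraries was the FGF9 transcription start. There was 1 wild-type library from forebrain and 1 from hindlimb, both of embryonic day 15. The submitters' processing notes name BWA for read mapping, with its version not given in the sources used here.

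The table analysed here was the gene annotation deposited with the series for the mole build talOcc3. It has no column for either library, and 4C contact values per fragment were not analysed here. The planned side-by-side account of forebrain and hindlimb contacts was therefore not made, and sequencing depth per library is unknown. A talOcc3 sequence was not used here either, so the viewpoint primers and the restriction sites were not placed. The annotation gives the first and last base of each gene, transcript and coding exon, counted from 1, on scaffolds that are cited below by their number. Per the file's second column, the models came from EVM (a program that combines several lines of evidence into 1 model), from exonerate (a protein or transcript aligner) or from a source named ALN. The deposited score of a transcript was assigned by the authors to its match with a named target transcript of another annotation, whose matched part is also recorded. How the score was calculated is not given in the sources used here, so scores were compared only between models of 1 symbol.

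Gene models were read as deposited. A symbol was the model name without its copy suffix. Models named by a LOC identifier or only by a model number counted as genes but carried no symbol. Each gene had 1 transcript, so coding exons and coding length came from that transcript, and no untranslated region was read. Scaffold length was taken as the last annotated base. Gene start meant the 5′ end of the model on its strand, and a distance between genes was measured from start to start unless edges are named. Gene density was the number of other models that started within 1 Mb of a gene's start. An intergenic gap was a stretch between merged neighbouring models.

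Gene order was measured against an order of 196 genes of human chromosome 13 and another of 20 genes around SALL1 on human chromosome 16, both written from general knowledge before the data were examined. A pair of successive listed genes counted as kept when both lay on 1 scaffold within 2 Mb with fewer than 5 other listed genes between them. This measure does not read the turning of a short stretch within a block. Where a symbol had several models, the one nearest to its listed neighbours was used. Further lists, fixed at the same time, held the FGF family, FGF receptors, testis and ovary pathways, steroid synthesis, and limb or forebrain regulators, 315 symbols over 8 lists in all. For each list, the share of symbols with at least 2 models was compared with that of all other symbols by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 8 lists. Percentiles of FGF9 among all genes are descriptions of 1 genome annotation and carry no p-value.

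A RefSeq gene table of the later mole build MPIMG_talOcc4v2.1 gave names and the order of neighbours. Its start positions served to order genes, to find where a sequence ends and to apply the 2 Mb limit within that build, and none are printed. It holds 31603 genes without sequence names, and a sequence was taken to end where the start position fell, which gave 461 sequences. Sequences that follow each other without such a fall are read as 1, so numbers of pairs on different RefSeq sequences are lower bounds. Symbols were matched exactly: 13999 of 16075 distinct deposited symbols were found in it. Agreement of neighbours was the share of adjacent deposited pairs, among symbols with 1 model in both tables, that were also adjacent in RefSeq, with a 95% Wilson interval that covers counting error only.

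The text names genes by a rule fixed before the data were examined: FGF9 with its 10 nearest models on each side, SALL1 with its 3 nearest, the genes beside order breaks at the FGF9 block, listed genes with at least 2 models, up to 15 listed genes without a model, and the 5 symbols with most models. Some genes that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen. The routines were tested on simulated data. They called 765 of 765 planted order breaks with 0 calls elsewhere, recovered the planted model number for 200 of 200 symbols and merged 200 of 200 fragmented symbols. No simulated run was as short as the shortest real ones, no simulated neighbours lay over 2 Mb apart, and the planted fragments shared no target bases. These tests therefore checked the code, and not its accuracy for short runs, long distances or partly overlapping fragments. Alternatives covered windows, distance limits, symbol-only and length filters, scaffold length and rules for merging models. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.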

Results

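The series was made to determine the regulatory domain of FGF9, a growth factor that promotes testis differentiation, in a mole whose females carry ovotestes. Its 2 libraries, 1 from forebrain and 1 from hindlimb of embryonic day 15, share the FGF9 promoter as viewpoint. With 1 library per tissue there are no replicates. What follows describes the genes around that viewpoint in the deposited annotation of build talOcc3, where each value belongs to 1 assembled genome and the precision is set by the assembly and its gene models. The annotation held 23336 gene models on 2074 scaffolds, each with 1 transcript. Of these models, 20411 (87.5%) lay on the 57 scaffolds whose annotation reached at least 1 Mb. A gene symbol was carried by 21076 models, which made 16075 distinct symbols. EVM contributed 14981 models with a median of 8 coding exons, exonerate 5944 with a median of 1, and ALN 2411 with a median of 2. Single-exon models made up 0.494% of the EVM models and 79.4% of the exonerate models.

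The first question was which genes border the viewpoint. FGF9 lay on the minus strand of scaffold 38, from 11731991 to 11761319. Its model, from exonerate, had 3 coding exons of 277, 104 and 243 bases, 624 coding bases in all, and spanned 29.3 kb. On the promoter side, MICU2, a regulator of mitochondrial calcium uptake, was the nearest gene, at 11893652 to 11939441 on the plus strand. The edges of FGF9 and MICU2 were 132 kb apart. Beyond MICU2 followed ZDHHC20, MRPL57, SKA3, SAP18, a single-exon SYPL1 model, the Hippo pathway kinase LATS2, a single-exon RPL12 model and a pair of XPO4 models. These 10 models ended within 0.732 Mb of the FGF9 start. On the other side, the nearest gene was RUBCNL, a Rubicon-like autophagy gene, at 10381222 to 10406007 on the plus strand. It started 1380 kb from the FGF9 start, 10.4 times as far as MICU2. The models beyond it included LRCH1, ESD, the serotonin receptor gene HTR2A, a single-exon CCDC59 model, SUCLA2, MED4, ITM2B and the tumour suppressor RB1, and the 10 models on this side reached back 3.07 Mb.

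**Figure D1:**
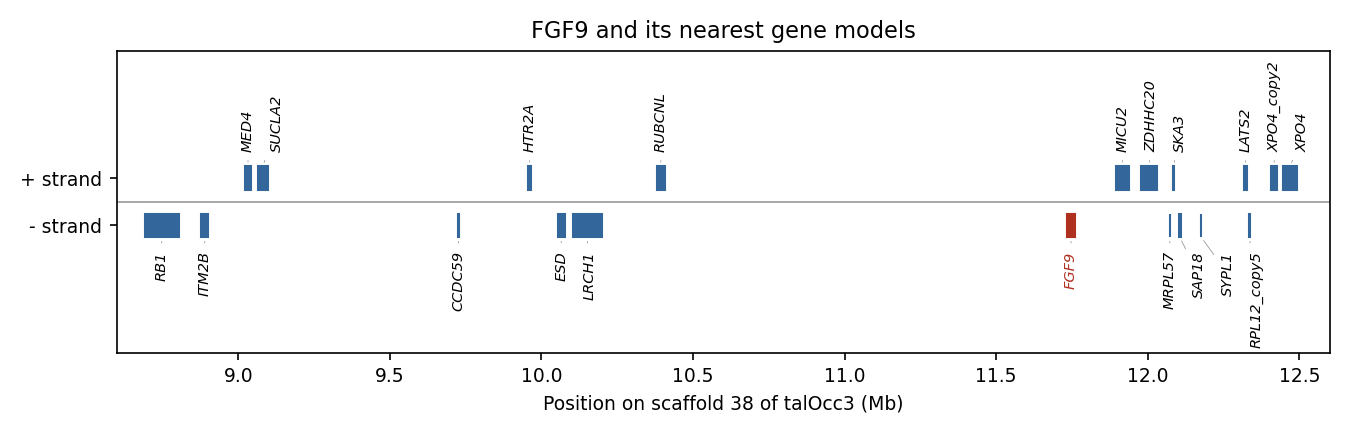
Map of FGF9 (red) and its nearest gene models as named in the text (blue) along scaffold 38 of talOcc3, with position in Mb on the horizontal axis and the strand of each model as its row. Boxes span first to last coding base to scale, and the stretch from RUBCNL to FGF9, 1.33 Mb long, holds no model.

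FGF9 was bordered on its 3′ side by a long stretch without deposited gene models. The gap between RUBCNL and FGF9, from 10406008 to 11731990, measured 1.33 Mb and was the longest of the 110 gaps on its scaffold. Over all scaffolds, 59 of 20412 intergenic gaps (0.289%) were as long or longer, and the median gap was 16.3 kb. The gap on the promoter side, to MICU2, was equalled or exceeded by 2392 of the 20412 (11.7%). These are shares of gaps and not of genes, and a gene can border a gap on each side. Within 1 Mb of the FGF9 start there were 13 other gene starts, all on the promoter side and 0 on the RUBCNL side, against a median of 25 for all genes. As few or fewer were found for 6409 of 23336 genes (27.5%), so the whole window was not extreme although the longer gap was. Ranked only among the 18378 genes at least 1 Mb from both ends of their scaffold, an alternative chosen after seeing the data, the share was 18.2%, 1.51 times lower.

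SALL1, a zinc finger gene of limb and kidney development for which viewpoint primers are also given in the labels, served for comparison. It lay on the plus strand of scaffold 26, from 26502895 to 26507793, with 2 coding exons and 3876 coding bases. TOX3 was the nearest gene on the lower side, across a gap of 913 kb that 163 of 20412 gaps (0.799%) equalled or exceeded, and CHD9 followed with 2 models on opposite strands. On the other side came CYLD, with 194 kb between the edges, then NOD2 and SNX20. SALL1 had 1 gene start within 1 Mb on the TOX3 side and 12 on the CYLD side.

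The series title speaks of rearrangements, and the next comparison asked where gene order in the mole departs from that of human chromosome 13. Of 196 listed genes, 189 had a model and gave 188 successive pairs, of which 175 were kept and 13 were not. The first 19 listed genes, from MPHOSPH8 to FGF9, lay in unbroken order on scaffold 38 from 11731991 to 13621409. At the FGF9 end of this block, RUBCNL and LRCH1 came next, and LRCH1 stands 100 places after FGF9 in the listed human order. The far end of the block, MPHOSPH8, was followed by an RPL9 model and, with 90.4 kb between the edges, by PARP4, 25 places further on in the list.

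The pair LCP1 and LRCH1, neighbours in the human list, was broken under 6 of 6 settings. MICU2 and FGF9 were kept under 6 of 6. Only the setting with the RefSeq gene order could have differed, and it gave the same calls. The others reuse the deposited positions, where neither call can change with the limits used. LCP1 started at 52346054 on scaffold 6. LRCH1, on scaffold 38 at 10102629 to 10198983, was separated from FGF9 only by RUBCNL, which was not on the fixed list. Listed ends were also exchanged further along. In the human list, ELF1 follows SLC25A15, and SUGT1 follows CKAP2 after HNRNPA1L2, which is described below. Between the edges of SLC25A15 and THSD1 on scaffold 38 lay 122 kb with 2 models. THSD1, in place 154 of the list, lay nearer to SLC25A15 than CKAP2, the last gene of that run, in place 156. Between the edges of ELF1 and SUGT1 on scaffold 6 lay 3.95 kb with 0 models. In the RefSeq table of the later build, 0 genes with a symbol lay between ELF1 and SUGT1, and 0 between SLC25A15 and THSD1. The latter pair had 1 protein-coding gene without a symbol between them there. This argues against wrong joins made in the deposited build alone at these 2 places. Wrong joins carried through both builds were not tested, and one human order cannot say in which lineage the order changed. THSD1, too, was chosen after its position was seen.

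Of the 13 pairs that were not kept, 9 lay on different scaffolds, 3 exceeded 2 Mb without a listed gene between them, and 1 had other listed genes between. Of the 9, 2 came from 1 listed gene, HNRNPA1L2, whose model lay apart from all other listed genes of this order on scaffold 2 and which stands between CKAP2 and SUGT1 in the list. It is named because its position was seen. In the RefSeq order, whose sequence ends are inferred and can be missed, 0 pairs lay on different sequences, 6 of 10 broken pairs had listed genes between and 4 exceeded 2 Mb, and 5 of the 13 pairs were broken in the deposited scaffolds only. The pair with listed genes between was RNF219 and RBM26, and RNF219 ended at 74469514, the last annotated base of scaffold 6. The 3 pairs over 2 Mb were OLFM4 and PCDH17 at 2.98 Mb, PCDH20 and PCDH9 at 3.40 Mb, and SPRY2 and SLITRK1 at 2.04 Mb, all named after their distances were seen. The SALL1 segment kept 17 of 18 pairs. Its only break, between ADCY7 and BRD7, parted a block of 4 listed genes, from N4BP1 to ADCY7, from the other 15, with the starts of ADCY7 and BRD7 18.4 Mb apart on scaffold 26. SALL1 stayed beside TOX3 and CYLD.

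**Figure D2:**
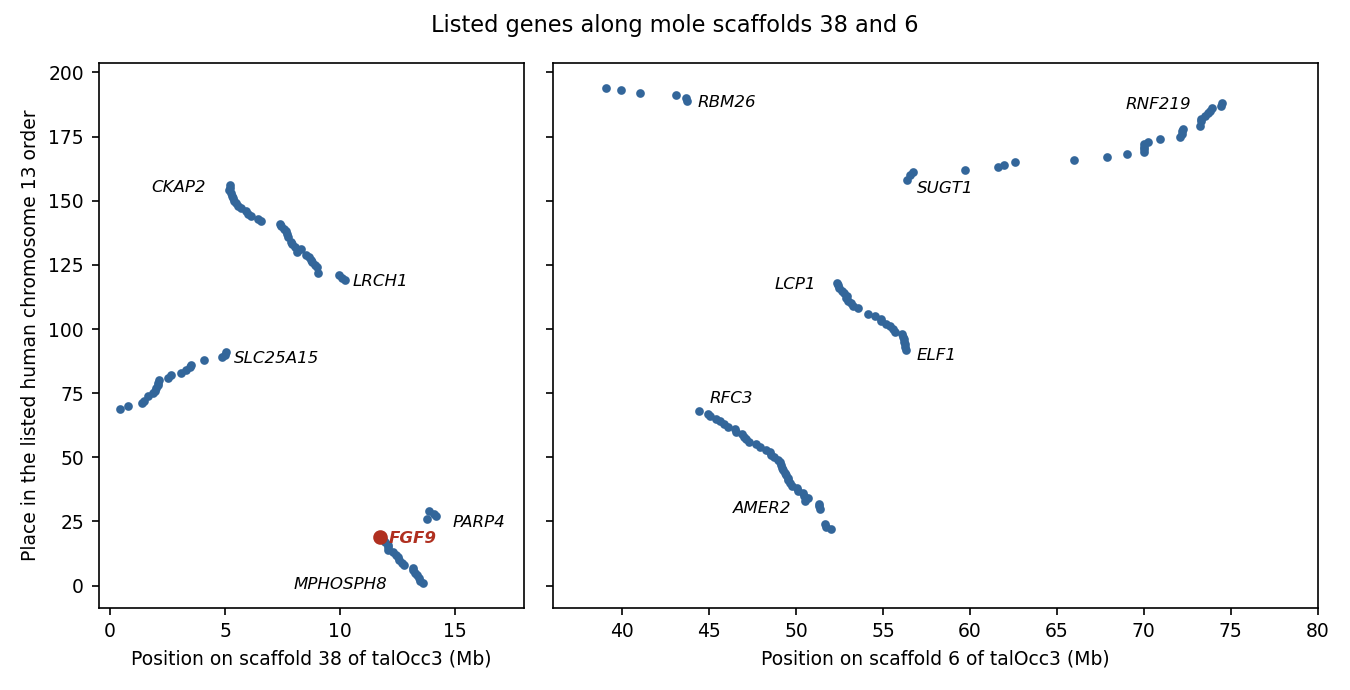
Start position in Mb of the listed genes on scaffolds 38 (left) and 6 (right) of talOcc3 against its place in the listed human chromosome 13 order, 1 point per gene shown and FGF9 in red. Runs that fall or rise without a step are stretches of kept order, and FGF9 sits at the end of the run from MPHOSPH8, beside LRCH1, the first gene of the run to CKAP2.

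The RefSeq table of the later build was then set against the deposited models. Of 12085 neighbouring deposited pairs with 1 model per symbol, 11587 (95.9%, Wilson 95% interval 95.5 to 96.2%) were also neighbours there, and 115 or more lay on different sequences. RefSeq kept 179 of 189 chromosome 13 pairs, and 8 pairs were broken in both orders, LCP1 and LRCH1 among them. Between FGF9 and RUBCNL it placed 4 features, all of them long non-coding RNA genes without a symbol. Of the 20 nearest symbols to FGF9, 16 were the same in both tables.

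Gene copies were counted because a symbol with several models can be a duplication or a split gene. In the steroid synthesis list, CYP17A1, which encodes a hydroxylase and lyase needed for androgen synthesis, had 3 models in tandem on the minus strand of scaffold 11, all within 44.3 kb. The model without a copy suffix lay at 45139044 to 45144553 with 8 coding exons, 1533 coding bases and a deposited score of 1476. The model CYP17A1_copy2, at 45100228 to 45105611, had the same 1533 coding bases, 8 of 8 coding exons of equal length and a score of 1366, 92.5% of the best. CYP17A1_copy3, at 45117841 to 45121591, had 6 coding exons, 1011 coding bases and a score of 904. Its last 5 exons matched the full models in length, and its target match began at base 698 where theirs began at 173. The gaps between the models measured 12.23 kb and 17.45 kb, and the group was bordered by WBP1L and by BORCS7, which a TUBA1B model overlaps.

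**Figure D3:**
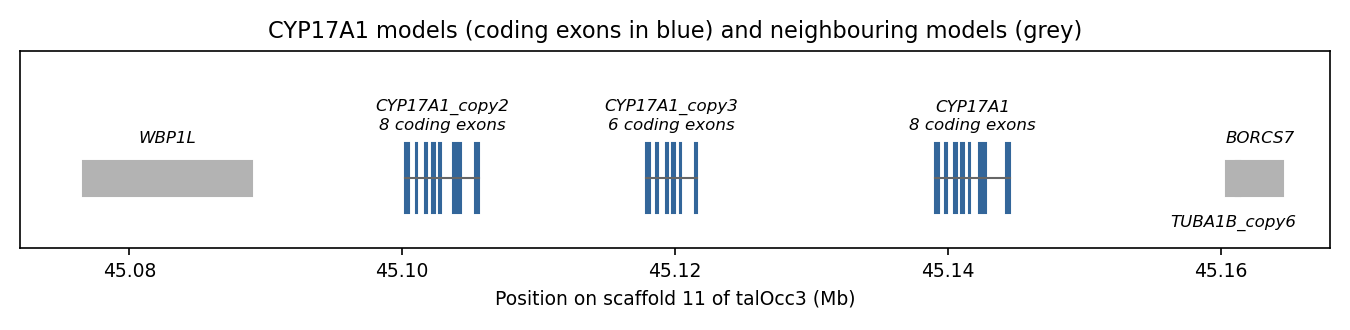
CYP17A1 models along scaffold 11 of talOcc3 in Mb, with coding exons as blue boxes to scale and neighbouring models as grey boxes from first to last base, of which TUBA1B_copy6 overlaps BORCS7. The outer models have 8 coding exons each, and the middle one has 6.

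Over all 8 lists, 28 of 294 symbols with a model had at least 2. The FGF family had 0 among its 19 members with a model (Fisher's exact test, two-sided, adjusted p = 0.688 against 14.6% of all other symbols), and the FGF receptors had 0 of 4 (adjusted p = 1.0). The testis list had 1 of 22, SOX10 (exact test, adjusted p = 0.688), the ovary list 1 of 15, the WNT pathway gene AXIN2 (adjusted p = 0.950), and the limb and forebrain list 1 of 18, the hindlimb regulator TBX4 (adjusted p = 0.801). Steroid synthesis had 2 of 15, CYP17A1 and CYB5A (exact test, adjusted p = 1.0), and the SALL1 segment 1 of 19, CHD9 (adjusted p = 0.688). The chromosome 13 order had 22 of 189 (11.6%, exact test, adjusted p = 0.688, raw p = 0.299). No list passed this exact test. Except for the chromosome 13 order, the lists are too small for a lower share to pass: with 0 symbols of at least 2 models, the raw p would be 0.0632 in the testis list and higher in the other 6.

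Model structure separated some of these cases and not others. The 2 AXIN2 models, with 7 and 2 coding exons, matched separate parts of the target, as did the pairs of TBX4, XPO4, ALG11, DIAPH3, GPC6 and SOHLH2, and the 2 CHD9 models overlapped. Each of these pairs lay on 1 scaffold except that of ALG11, whose models lay on 2 scaffolds, 1 of them with a single coding exon. CYB5A had 1 single-exon model and 1 with 2 coding exons, on different scaffolds. The second SOX10 model lay on a small scaffold and scored 58.7% of the best. Among chromosome 13 genes, HMGB1, a chromatin protein, had 7 models of which 6 had 1 coding exon, and TPT1, a translationally controlled protein, had 8 of which 6 had 1. SUPT20H had 4 models, of which 3 had 1 coding exon, and 2 after models of separate target parts were merged. UFM1 had 3 models, of which 2 had 1 coding exon. ALG5, ATP8A2, CKAP2, DIS3, DNAJC15, EXOSC8, MTMR6, POLR1D, POMP, SLC25A30, SPRYD7, TNFRSF19 and TSC22D1 had 2 each, of which 1 had a single coding exon in ALG5, CKAP2, DIS3, EXOSC8, POMP, SPRYD7 and TSC22D1. When models of separate target parts counted as 1, a rule chosen after seeing the data, 20 listed symbols kept at least 2 models, CYP17A1 with all 3.

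Of 315 listed symbols, 21 had no model under that name, of which 4 had one under another symbol (ACOD1 for IRG1, CNMD for LECT1, LHFP for LHFPL6 and SPG20 for SPART). These 4, outside the naming rule, are named because their other symbols were seen. In the family and pathway lists, 14 had no model, of which IRX3 is also on the SALL1 order list. RefSeq lists 10 of these by symbol, DHH, FGF3, FGF19, FGFRL1, FOXL2, IRX3, PTGDS, SALL3, SHH and SOX8, and does not list AKR1C3, CYP11B1, FGF2 or HSD3B2. Genome-wide, the symbols with most models were COX1 with 80, ND1 with 74, CYTB with 71, TRIM38 with 63 and BMS1P20 with 62. COX1, ND1 and CYTB are names of mitochondrial genes, and 98.8%, 98.6% and 97.2% of their models lay on scaffolds shorter than 1 Mb. The share was also high for TRIM38, at 90.5%, and BMS1P20, at 79.0%.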

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

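Alternatives that used RefSeq order, merged models by overlap or by target part, ranked only genes away from scaffold ends, merged overlapping models for density, lifted the limit on listed genes between, or placed symbols by their best score were chosen after seeing the data. Model number, broken chromosome 13 pairs (10 to 19 against 13), and listed symbols with at least 2 models (20 to 28 against 28) stayed within 1.5 times. Measured between gene edges, RUBCNL lay 1326 kb from FGF9 in place of 1380 kb, by construction. The share of genes with as few or fewer neighbours as FGF9, 27.5%, was 26.0% with a 0.5 Mb window, 33.7% with 2 Mb, 24.8% with symbols only, 28.3% with coding length of at least 300 bases, 18.2% among genes at least 1 Mb from both scaffold ends and 29.0% with overlapping models merged. Agreement of neighbours with RefSeq fell from 95.9% to 92.4% with symbols of several models placed by the highest score. The cause was not tested for these shares. In the steroid synthesis list, 2 symbols with at least 2 models made up 13.3% against 14.6% of other symbols, but 2 made up 14.3% against 13.2% on scaffolds of at least 1 Mb only, and 2 made up 13.3% against 10.1% with models of separate target parts merged. The direction turned in these settings. With coding length of at least 300 bases, 1 of 14 symbols (7.14% against 12.7%) had at least 2. No setting passed the test (adjusted p from 0.811 to 1.0).

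The planned rule for split models requires another, longer model of the symbol, so it cannot lower the number of symbols with at least 2 models and says nothing about stability. Merging all transcripts moved nothing, since each gene has 1. Not run were the alternative for 4C contacts, whose values were not analysed here, and any change to primer placement. With 1 library per tissue, no replicate was left out. The precision of positions and copy numbers is limited by assembly and annotation, which no depth measure here describes.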

Other observations

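CYP17A1 was the only listed gene among 53 symbols with a tandem of at least 2 multi-exon models that each covered 90% or more of the longest target match, within 100 kb on 1 strand. With a score of at least 80% of the best also required, 34 symbols remained, 6 of them olfactory receptors. Several others, chosen after their values were seen, belong to defence and lipid metabolism. PRF1, which encodes the pore-forming perforin of cytotoxic lymphocytes, had 4 models of 1668 coding bases on scaffold 11 between 21093278 and 21472992, the weakest at 97.8% of the best score, although the intron of PRF1_copy4 made that model 193 kb long. UBD, a ubiquitin-like gene induced by interferon, had 4 on scaffold 48. CYP4A11, a fatty acid hydroxylase gene, had 3 with 12 coding exons each on scaffold 2, at 96.6% or more of the best score. FSHB, the follicle-stimulating hormone beta gene, had 2 models, but the second scored only 39.2% of the first.

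Single-exon models were more frequent among models with a copy suffix, with exceptions. Of the suffixed models of symbols with several, 54.1% had 1 coding exon, against 18.4% of those without a suffix. For 163 symbols, 6.94% of the 2348 with at least 2 models, the model without a suffix had 1 coding exon while a suffixed model had 3 or more. HMGB1 and TPT1 are examples, with the models without a suffix on scaffold 5. The models used for the chromosome 13 order, picked as nearest to their listed neighbours, lay on scaffold 6, HMGB1_copy2 with 4 coding exons and TPT1_copy5 with 7. A further HMGB1 model with 1 coding exon, HMGB1_copy7, lay in the same run of scaffold 6, at 51379651 to 51380245. The 163 also included 18 ribosomal proteins and olfactory receptors such as OR10G2, so these examples do not stand for all. For these 163 symbols, the unsuffixed name and the multi-exon model give different positions. Which of the models is the original gene was not tested.

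Of the tests below, those on wrong joins carried through both builds and on missing neighbourhoods were set before their values were seen, and the others after. FGF9 lies beside RUBCNL, with LRCH1 next, which stands 100 places away in the listed human order. A wrong join made in the deposited build alone is argued against by the later build, which has 0 genes with a symbol between FGF9 and RUBCNL, and protein-coding genes in between that lack a deposited model are argued against by its 0 protein-coding genes there. A wrong join carried through both builds stays open: builds agree for 95.9% of neighbours in general, and reads or contacts across the join were not analysed here. A rearrangement in the mole lineage may account for the pattern, as a hypothesis that no group of samples here tests, and one human order cannot say in which lineage the order changed.

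The tandem of 3 CYP17A1 models is not 1 gene split into several models, since target matches of every pair overlapped by 100% of the shorter. It does not look like retrocopies of a processed transcript, since no model has fewer than 6 coding exons. Alleles of 1 locus assembled side by side stay open for 2 of the 3 models, since a diploid genome has no more alleles of a locus. They would leave at most 1 feature without a symbol between BORCS7 and WBP1L in RefSeq. RefSeq has 4 features there, 2 protein-coding and 2 pseudogenes. None has a symbol, so what they are is not given and their number cannot decide. Duplication of the gene is a candidate explanation that sequence identity, not computed here, would bear on. No biological explanation was tested.

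Among genes of the family and pathway lists that have no model, absence from the species is argued against for the 10 that RefSeq lists and cannot be told apart from a change of name for the 4 that it does not list, because a missing symbol excludes nothing. Whether the whole neighbourhood is missing from the deposited build was asked of the 10: for 80% of them (8 of 10, Wilson 95% interval 49.0 to 94.3%) both RefSeq neighbours lay on 1 deposited scaffold within 2 Mb. The bound set beforehand against a missing neighbourhood was at least 80%, which the share just meets. For these 8, a missing neighbourhood is argued against. Since 2 of the 10 go the other way and the interval is wide, the group as a whole was still left undecided. The interval treats the 10 as a sample, although they are all the symbols of this kind. For SHH, the neighbours EN2 and LMBR1 stood 456 kb apart with no SHH model between them, and for FOXL2, MRPS22 and PIK3CB stood 530 kb apart. FGF19 and SOX8 were the exceptions. A gap in the gene models may therefore explain part of the list, so a missing model here is no evidence of a lost gene.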
